A study of Mus musculus with 4 samples.

How the data were processed

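Gene expression was measured in primary myoblasts of adult (8 months) and aged (23 months) DBA/2JNIA mice on Affymetrix MG-U74Av2 arrays, which read each transcript with 1 or more probe sets, each a group of short oligonucleotides. There were 2 arrays per age, and per the labels each sample was a pool of cells from 4 mice.

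The values used were the deposited intensity of each probe set on each of the 4 arrays. The software behind them is not given in the sources used here. The deposited intensity values were on a linear scale and not centred per gene, since they ran from -7958 to 160387, and the authors had scaled the arrays to a common target, since the means after trimming 2% at each end were 1501 on every array and differed by at most 0.00761%. Values below 0 made up 21.7% and 21.7% of the adult arrays and 22.3% and 21.2% of the aged arrays, as background or mismatch subtraction gives. The array medians were 481, 486, 482 and 487. For arrays there is no read depth, and the number of arrays limits the precision.

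The columns were used without further normalization, because their trimmed means agreed within 5%. Values below a floor of 187 units were set to it, and log2 was taken. The floor had been fixed as the 20th percentile of all values, but that percentile was -15.4 and has no log, so the 20th percentile of the values above 0 was used in its place, before any test was run. Between 37.1% and 37.9% of the values on an array lay at or below this floor. A fold change of a gene near the floor is therefore understated, and a gene at the floor on both arrays of an age has only a bound, the mean log2 value of the other age against the floor, written as at least so many fold. Probe sets whose mean floored value lay above 233 units (the 40th percentile of all values) were tested, 7823 of 12488, after 66 control probe sets were left out, and 6812 of those tested were above the floor on all arrays. Means ± SD are of the deposited intensities, and log2 fold changes and folds are of the floored values.

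Gene symbols came from the platform annotation, which lists 1 gene for 10855 probe sets, several for 396 and none for 1237. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which held 10839 of them and changed 0. No genome build is named in the sources used here, so no coordinates are given. The tested probe sets with a single symbol covered 5856 genes, and 807 tested probe sets had no single symbol.

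Aged and adult arrays were compared with lmFit and eBayes of limma (version 3.58.1, R version 4.3.3) on the log2 values, aged minus adult, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. As a rule without a variance estimate, probe sets at least 2-fold apart in all 4 pairs of an aged and an adult array were counted, with the same count for the other 2 splits of the arrays. Of 24 gene lists, 23 with at least 5 measured genes were tested with camera at an inter-gene correlation of 0.01 on 1 probe set per gene, the one with the highest mean, and adjusted over the lists. Measured genes are those with a tested probe set, so the dim members of a list are left out. With the correlation estimated per list, 0 of the 7 passing lists held, and 3 had an unadjusted p under 0.05. That option rests on the few residual degrees of freedom of 4 arrays, which by itself raises the p-values. The estimate lay below 0.01 for muscle differentiation (-0.018), cell cycle (0.0035), growth arrest (-0.0032), extracellular matrix (-0.023) and smooth muscle (-0.16). It lay above 0.01 for interferon response (0.023) and glycolysis (0.21). The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said otherwise.

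Genes were named by a fixed rule. Of probe sets with 1 symbol, taken as the 1 with the highest mean per gene, with all 4 values above the floor and both aged values on one side of both adult values, the 12 highest and 12 lowest log2 fold changes among those passing were named, and free places went by unadjusted p to probe sets 2-fold apart in all 4 pairs. In addition, up to 4 members per list with the smallest unadjusted p, the 3 brightest genes per direction with the other age at the floor, and 13 genes given whatever their p (Myod1, Myf5, Myog, Des, Pparg, Cebpa, Fabp4, Cdkn2a, Cdkn1a, Tgfb1, Tgfb2, Smad3 and Wnt10b) were named. Other probe sets of a named gene were mentioned where they disagreed.

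The procedure was tested on simulated data with 12488 probe sets and 200 changed ones per run, in 10 runs with the noise of these arrays. It called 0.139% of probe sets changed 2-fold, 34.7% of those changed 4-fold and 58.8% of those changed 8-fold, and of the calls 1.81% were on unchanged probe sets. A changed probe set kept the noise of its level before the change. Lowered probe sets thus had the noise of brighter ones and raised ones that of dimmer ones. The shares called are therefore only a rough guide to real changes of that size. A list of 40 genes raised 1.5-fold passed camera in 10 of 10 runs, and 0 of 200 unchanged lists passed. The noise was drawn separately for each probe set, so the simulated genes were not correlated. These runs therefore cannot show how often unchanged lists of correlated genes would pass.

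The alternatives were quantile normalization, scaling to equal medians, other floors, a pseudocount in place of the floor, no filter or a stricter one, a variance trend, a plain equal-variance test, the replicate number as a block, each array left out in turn, an estimated inter-gene correlation, the self-contained set test fry, the mean of a gene's probe sets, and other fold limits. A floor at the 30th percentile of the values above 0 and a run on probe sets above the floor on all arrays were added after seeing the data.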

Results

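RNA of primary myoblasts, the muscle precursor cells that are grown in culture from skeletal muscle and that can fuse into myotubes, was measured on 4 oligonucleotide arrays. Cells came from mice of the DBA/2JNIA strain. Adult myoblasts were from animals of 8 months and aged myoblasts from animals of 23 months, with 2 arrays per age and a pool of 4 mice behind each array. The labels do not say whether the 2 arrays of an age hold separate pools, so the p-values measure only the spread between these arrays, which may be technical. Each array gave 12488 probe set intensities in linear, scaled units. The array medians were 481 and 486 for the adult cells and 482 and 487 for the aged cells, and between 21.2% and 22.3% of the values on an array lay below 0. With 2 arrays per age, the number of arrays limits the precision of every value. The comparison of the 2 ages asked how muscle precursor cells differ in gene expression late in life. A further interest of the study, as far as it is known, was whether genes of fat cells and of TGF-beta and Wnt signalling differ in the aged myoblasts.

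Genes of the muscle contractile apparatus were among those with the highest rise in the aged myoblasts, while genes of the cell cycle were lower. Acta1, the skeletal muscle alpha-actin, rose 16.1-fold, from 1059 ± 63.6 intensity units in adult cells to 16994 ± 331 in aged cells (mean ± SD, n = 2 arrays each; log2 fold change 4.01 ± 0.12, SE; limma adjusted p = 0.0169). Acta2, the smooth muscle alpha-actin, rose 5.67-fold, from 4274 ± 555 to 24143 ± 597 (adjusted p = 0.0425). Myl4, an embryonic and atrial myosin light chain, rose 5.83-fold (adjusted p = 0.0324). Mybph, a myosin-binding protein, rose 5.18-fold (adjusted p = 0.0315). Myh3, the embryonic myosin heavy chain, rose 4.59-fold (log2 fold change 2.20 ± 0.15, SE; adjusted p = 0.0440).

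The other genes among the 12 named for their rise were not muscle-specific. These 12 had the highest rise, by brightest probe set, among genes that passed with all 4 values above the floor. Cd24a, a small cell surface glycoprotein, rose 6.48-fold (adjusted p = 0.0440). Gsn, the actin-severing protein gelsolin, rose 4.27-fold and Anxa3, a calcium-dependent membrane-binding annexin, rose 4.04-fold (adjusted p = 0.0372 and 0.0380). Lmo7, 2210016F16Rik and Ifi27 rose by log2 fold changes of 2.09, 2.11 and 1.83 (adjusted p = 0.0425, 0.0430 and 0.0430). A probe set annotated to Ctse, the aspartic protease cathepsin E, rose 10.1-fold, from 7938 ± 1321 to 79689 ± 8785 (adjusted p = 0.0377). A further Ctse probe set rose by a log2 fold change of 2.46, but the third lay below the floor on all 4 arrays, so the gene behind the signal is uncertain.

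Of genes that fell in the aged myoblasts and were above the floor on all 4 arrays, Msln, the cell surface protein mesothelin, had the lowest log2 fold change, -3.16 ± 0.19 (SE), from 4125 ± 787 to 459 ± 41.9 (adjusted p = 0.0425). Kcnn4, a calcium-activated potassium channel, was 6.64-fold lower (adjusted p = 0.0482). Reln, the secreted glycoprotein reelin, was 6.01-fold lower, from 3315 ± 5.16 to 551 ± 2.33 (adjusted p = 0.0265), although its other probe set gave a log2 fold change of -0.20 (adjusted p = 0.781). Mdm4, an inhibitor of p53, was 5.68-fold lower, from 8087 ± 34.5 to 1426 ± 59.4 (adjusted p = 0.0265), and its other probe set, at the floor in aged cells, gave -0.78 as a bound (adjusted p = 0.115). Ccne2, the cyclin E2 that acts at entry into DNA replication, was 4.80-fold lower, from 1080 ± 110 to 225 ± 16.8 (adjusted p = 0.0430). D17H6S56E-5, Rgs16, an inhibitor of G protein signalling, and Cenpv, a centromere protein, were 4.09-fold, 3.42-fold and 2.67-fold lower (adjusted p = 0.0467, 0.0440 and 0.0477), although the other Cenpv probe set gave a log2 fold change of -0.59 (adjusted p = 0.411). Mtm1, the phosphoinositide phosphatase myotubularin, was 2.72-fold lower by its brighter probe set (adjusted p = 0.0477), whereas its dim probe set, at the floor in adult cells, gave a log2 fold change of at least 0.58 (adjusted p = 0.234). Only 9 genes in this direction passed with all 4 values above the floor. C5ar1, Il18rap and Zzz3, next by unadjusted p among those 2-fold apart in every pair of arrays, did not pass, with log2 fold changes of -2.18, -1.18 and -1.19 (adjusted p = 0.0533 each).

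**Figure D1:**
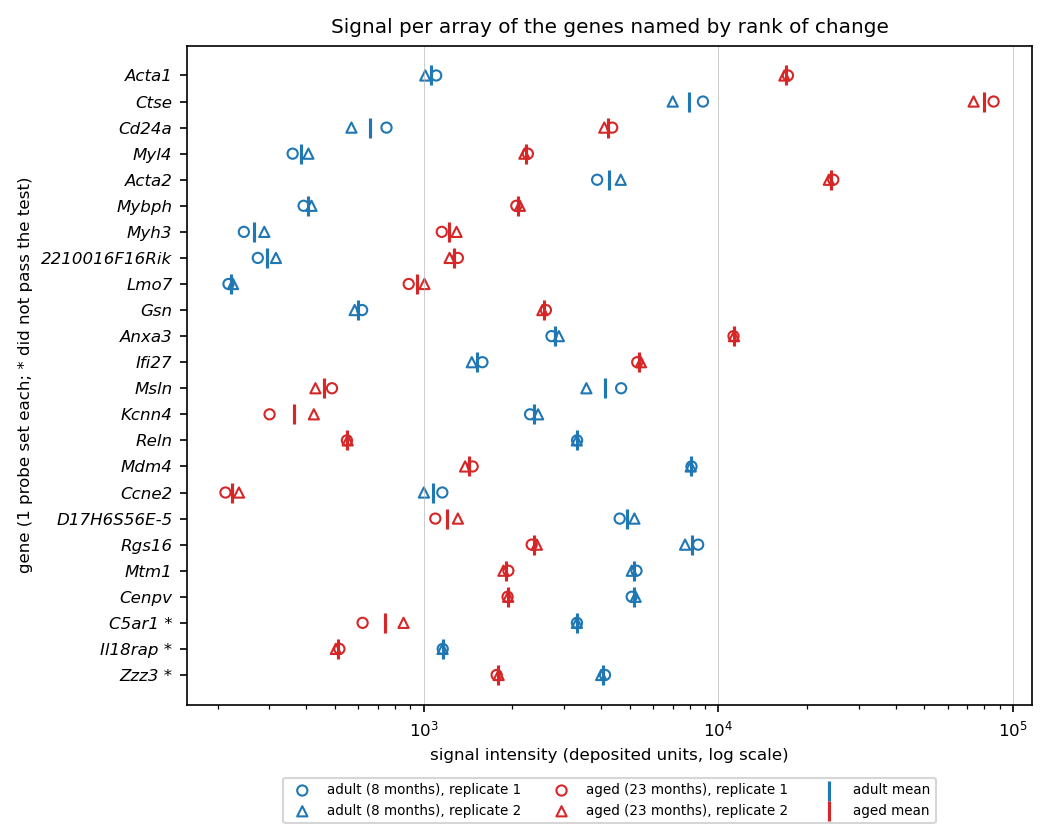
Signal intensity (horizontal axis, deposited units, log scale) of the 24 genes named by rank of change (vertical axis), with 1 point per array in blue for adult and red for aged myoblasts and a bar at each group mean of 2 arrays. Acta1 lies near 1059 on the adult arrays and near 16994 on the aged arrays, and in each of the 24 genes both aged points lie on one side of both adult points.

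Some transcripts were above the floor at only 1 age, the signal of the other age lying at or below the floor of 187 units on both arrays, so that only a bound can be given. Taking each gene by its brightest probe set, the brightest of those above the floor in aged cells were Car3, a carbonic anhydrase of skeletal muscle, at least 29.9-fold higher at 5591 ± 280 (adjusted p = 0.0124), Ccn2, the connective tissue growth factor, at least 23.9-fold higher at 4475 ± 230 (adjusted p = 0.0124), and Tnnc1, the slow and cardiac troponin C, at least 22.6-fold higher at 4251 ± 519 (adjusted p = 0.0177). The brightest in the opposite direction were AU020206, at least 16.3-fold lower in aged cells (adjusted p = 0.0265), Six2, a homeobox transcription factor, at least 6.73-fold lower (adjusted p = 0.0265), and Daglb, a diacylglycerol lipase, with a bound of 14.6-fold that did not pass (adjusted p = 0.0812). The adult arrays differed widely for Daglb, at 3144 ± 2196.

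Across all 7823 probe sets tested, 66 passed a Benjamini-Hochberg adjusted p of 0.05 in limma's two-sided moderated test, 41 higher and 25 lower in aged cells, from 61 named genes. All 66 were also at least 2-fold apart in every pair of an aged and an adult array, as were 284 probe sets in all (161 higher, 123 lower). The other 2 ways of splitting the 4 arrays into pairs gave 30 and 66, and limma passed 0 in them (219 and 242 at unadjusted p under 0.05). Each of those splits sets an aged beside an adult array, so an age difference adds to the spread within a side. Their counts are therefore no measure of chance. Between the ages, 1712 probe sets had an unadjusted p under 0.05, with 391 due by chance. Both aged values lay on one side of both adult values in 53.8% of probe sets, where chance gives 33.3%. Between single arrays, 691 probe sets were at least 2-fold apart for the adult pair and 410 for the aged pair. For an aged against an adult array the count ran from 813 to 1051. The ratio of 3' to 5' signal, a sign of RNA quality, was 1.09 and 1.18 for actin on the adult arrays against 1.25 and 1.28 on the aged arrays, and 0.869 and 0.807 against 1.03 and 0.902 for Gapdh. Bacterial control transcripts, which do not come from the cells, were split too. Aged to adult ratios of Dap, Lys and Phe were 1.12, 1.13 and 1.12 at the 3' end. At the 5' end they were 0.843, 0.953 and 0.886. Thr showed no such split (0.977 and 0.995). The ratios of actin and Gapdh therefore need not reflect the RNA of the cells. The count of passing probe sets depended on the variance model and the filter: it was 476 with a variance trend along signal level, 10 with a plain equal-variance test without eBayes, and 351 with a stricter filter on low signal. Without any 1 of the 4 arrays it was 0 in limma (903 to 1996 at unadjusted p under 0.05). There the other age supplies the spread of the lone array, so the 0 does not show dependence on that array.

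Muscle differentiation genes rose as a group in the aged myoblasts. Of 40 measured, each by its brightest probe set, 32 had a positive log2 fold change. Over all probe sets 6 passed as higher and 0 as lower, and adjusted over the list alone 20 were higher and 3 lower. The median log2 fold change was 0.83 (limma camera adjusted p = 1.5e-08, and adjusted p = 0.218 with an estimated correlation). With no filter, members at the floor on all arrays enter at 0 and the median was 0.32. With the floor at the 30th percentile of the values above 0 the median was 0.18. The 4 members with the lowest p were Acta1, Tnnc1, Mybph and Myl4. Dimmer probe sets of Actc1, Tnnt1 and Chrng also passed in limma, at log2 fold changes of 5.02, 2.82 and 1.87 (adjusted p = 0.0124, 0.0430 and 0.0482). That of Actc1 lay below the floor on both adult arrays, so its value is a bound, and its brightest probe set gave 1.82. The 3' to 5' signal ratios of actin and Gapdh, higher on both aged arrays, moved with age beside this list and each of the lists that follow. Myog, the transcription factor that starts terminal differentiation, stood at 483 ± 243 in adult and 2247 ± 130 in aged cells, a log2 fold change of 2.32 ± 0.41 that did not pass (adjusted p = 0.0961). Smooth muscle and pericyte markers rose too, with 5 of 7 measured genes positive and only Acta2 passing (3 higher adjusted over the list alone; median 0.92; adjusted p = 0.0215, and 0.447 with an estimated correlation). Mcam, at the floor on both adult arrays and at least 3.86-fold higher, did not pass, nor did Rgs5 and Tagln, at log2 fold changes of 0.92 and 0.64. The smooth muscle call was lost without adult replicate 1 or adult replicate 2 (adjusted p = 0.0733 and 0.0599), with no filter on low values (0.105), with the floor at the 30th percentile of the values above 0, which in effect also lifts the filter (0.0832), and when only probe sets above the floor on all arrays were used (0.0915).

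Myoblast identity genes did not shift as a group (20 measured, 11 positive and 9 negative, median 0.16, camera adjusted p = 0.195), and 0 passed over all probe sets, while 5 were higher and 2 lower adjusted over the list alone. Myod1, the determination factor of the muscle lineage, was close at 42443 ± 2375 and 39479 ± 1996 (log2 fold change -0.10 ± 0.12; adjusted p = 0.679). Myf5, a factor of undifferentiated myoblasts, was 4451 ± 141 in adult and 2312 ± 109 in aged cells (log2 fold change -0.95; adjusted p = 0.0684). The adhesion molecules Sdc4, Ncam1 and Cdh2 had log2 fold changes of 1.31, 1.06 and 0.78 (adjusted p = 0.0620, 0.0749 and 0.0830), although the other Ncam1 probe set gave 0.14 (adjusted p = 0.836). Des, the intermediate filament protein desmin, had 0.28 (adjusted p = 0.280).

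Genes of the cell cycle and DNA replication fell as a group. Of 66 measured, 60 had a negative log2 fold change and both aged values lay below both adult values in 51, with a median of -0.55 (camera adjusted p = 2.3e-12; adjusted p = 0.218 with an estimated correlation). Only Ccne2 passed over all probe sets, and 32 were lower and 0 higher adjusted over the list alone. Hmgb2, a chromatin protein of dividing cells, went from 7706 ± 537 to 3483 ± 43.9, Stmn1, a microtubule-destabilising protein, from 21315 ± 489 to 10627 ± 332, and Cdc6, which licenses replication origins, from 2744 ± 339 to 1142 ± 59.8 (adjusted p = 0.0593, 0.0620 and 0.0648). Growth arrest genes and p53 targets rose as a group (25 measured, 16 positive, median 0.32, camera adjusted p = 0.0166; adjusted p = 0.447 with an estimated correlation), and the call was lost without aged replicate 1 (adjusted p = 0.0672). Rb1, the retinoblastoma protein that restrains entry into the cycle, passed, at 763 ± 0.919 in aged cells and below the floor on both adult arrays (at least 4.08-fold; adjusted p = 0.0370), but its other probe set was below the floor on all 4 arrays. Adjusted over the list alone, 5 members were higher and 0 lower. Tob1, Foxo3 and Gadd45g had log2 fold changes of 1.33, 0.80 and 0.87 and did not pass. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 10259 ± 1345 against 13338 ± 508 (log2 fold change 0.38; adjusted p = 0.268), with overlapping arrays in its other probe set (0.29; adjusted p = 0.708), and Cdkn2a, the locus of p16 and p19Arf, was 851 ± 140 against 719 ± 202 (-0.26; adjusted p = 0.631, with a log2 fold change of 0.027 without aged replicate 2).

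Extracellular matrix genes rose as a group, with 28 of 41 positive, 11 higher and 1 lower adjusted over the list alone, and a median log2 fold change of 0.35 (camera adjusted p = 0.00044; adjusted p = 0.318 with an estimated correlation). That median was 0.039 with no filter, where members at the floor count as 0. It was 0 with the floor at the 30th percentile of the values above 0. Ogn, a small leucine-rich proteoglycan, and Postn, the matrix protein periostin, passed, both below the floor on the adult arrays and at 582 ± 6.08 and 584 ± 9.69 in aged cells (at least 3.11-fold and 3.12-fold; adjusted p = 0.0430 each), but the other Ogn probe set, at the floor on 3 arrays, gave a log2 fold change of 0.52 (adjusted p = 0.518). Nid1, a basement membrane protein, and P4ha1, a collagen prolyl hydroxylase, had log2 fold changes of 1.41 and 2.05 (adjusted p = 0.0533 each). Glycolysis genes rose as a group, with 14 of 15 positive and a median of 0.23, although 0 passed by their brightest probe set and 2 were higher adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.526 with an estimated correlation, and 0.0783 with the preset one without adult replicate 2). That median ran from 0.12 without adult replicate 2 to 0.35 without adult replicate 1. Pfkl and Pfkp, subunits of phosphofructokinase, stood at log2 fold changes of 1.39 and 1.76 (adjusted p = 0.0533 each), and a dimmer Pfkp probe set passed at 2.25 (adjusted p = 0.0467). The other named members, Hk1 and Ldhb, had 0.46 each. Interferon response genes passed narrowly, with 13 of 19 positive, a median of 0.42 and 0 passing by their brightest probe set (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0465; adjusted p = 0.506 with an estimated correlation). Its call held in only 4 of 14 alternative settings at the preset correlation, with adjusted p from 0.0313 to 0.189. The median was 0.27 without adult replicate 1 and 0 with no filter. A dimmer probe set of the member H2-K1 passed in limma at a log2 fold change of 2.05 (adjusted p = 0.0467). Tap1, a peptide transporter, and Ifi202b had log2 fold changes of 1.18 and 0.79, and Irf9, at the floor on both adult arrays, was at least 2.26-fold higher without passing, whereas Ifitm3, a membrane protein induced by interferon, had -1.31, from 16711 ± 1885 to 6730 ± 845 (adjusted p = 0.0686).

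**Figure D2:**
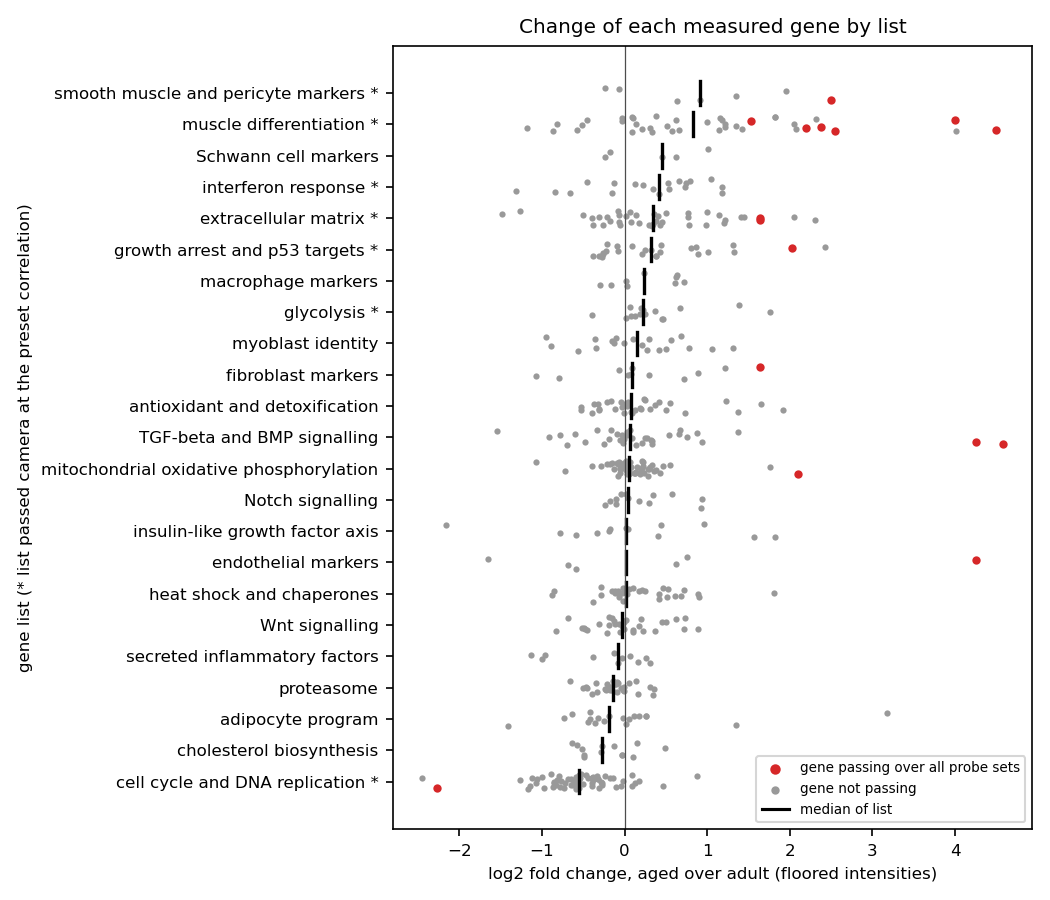
Log2 fold change of aged over adult myoblasts (horizontal axis) for each measured gene, by gene list (vertical axis, in order of the list median), with genes that passed over all probe sets in red, others in grey and a black bar at the list median. The medians run from 0.92 for smooth muscle and pericyte markers to -0.55 for cell cycle and DNA replication, and an asterisk marks the 7 lists that passed camera at the preset correlation.

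The adipocyte program did not shift as a group. Of its 28 genes on the array, 19 were bright enough to be tested. Among these 19, 8 were positive and 11 negative, and 0 passed over all probe sets (camera adjusted p = 0.650). The median log2 fold change was -0.19 (-0.09 without adult replicate 1) but the mean was 0.01. Lpl, the lipoprotein lipase, was the only member that passed when adjusted over the list alone, at 323 ± 132 in adult and 2804 ± 41.7 in aged cells (log2 fold change 3.18 ± 0.33; adjusted p = 0.0586 over all probe sets). Cebpd had a log2 fold change of 1.35 and Cebpa, a factor of fat cell differentiation, 0.26, or 0.091 without aged replicate 1 (adjusted p = 0.142 and 0.486), while Scd2 and Acly, enzymes of lipid synthesis, had -0.44 and -0.42 (adjusted p = 0.177 and 0.178). Pparg, the receptor that drives fat cell differentiation, and Fabp4, its fatty acid-binding target, were below the floor on all 4 arrays.

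TGF-beta and BMP signalling did not pass as a group either (35 measured, 20 positive, median 0.06, camera adjusted p = 0.195). It passed with the filter at the 60th percentile (adjusted p = 0.0421). In the planned test 2 of its members rose, and 3 were higher adjusted over the list alone. Ccn2, a target of TGF-beta, was at least 23.9-fold higher (adjusted p = 0.0124), and Eng, the co-receptor endoglin, was at 3571 ± 7.42 in aged cells and below the floor on both adult arrays (at least 19.1-fold higher; adjusted p = 0.0124). Smad7, an inhibitor of the pathway, with a log2 fold change of 1.37, and Bmpr2, at the floor on both aged arrays and at least 1.89-fold lower, did not pass. Tgfb1 and Smad3 were below the floor on all 4 arrays, and Tgfb2 was above it on 1. Wnt signalling had a median of -0.03 and a mean of 0.01 over 31 measured genes, with camera's direction up although 18 were negative (adjusted p = 0.903), and 0 passed by either adjustment. The lowest p-values belonged to Ccn4, Wnt7b, Fzd1 and Apc, at log2 fold changes of 0.51, -0.52, -0.45 and 0.74. Wnt10b, a ligand that holds back fat cell differentiation, was 1633 ± 364 against 1411 ± 57.1 (log2 fold change -0.19; adjusted p = 0.639, with a log2 fold change of 0.036 without adult replicate 1). Of its other probe sets, 1 was below the floor on all 4 arrays and 1 gave -0.36. Notch signalling had a median of 0.04 over 13 genes (adjusted p = 0.324), which was 0.21 without aged replicate 1.

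The remaining groups did not pass in the planned test. Mitochondrial oxidative phosphorylation had 36 of 54 genes positive and a median of 0.06 (camera adjusted p = 0.0886). It passed with no filter (adjusted p = 0.0177) and with the floor at the 30th percentile of the values above 0 (0.00829). Cox6a2, the muscle form of a cytochrome oxidase subunit, passed, at 888 ± 84.6 in aged cells with 1 adult array below the floor (log2 fold change 2.10; adjusted p = 0.0482). The brightest Atp5d probe set had a log2 fold change of 1.76 (adjusted p = 0.0533), while the probe sets of that gene ranged from -0.10 to 1.76 and a dimmer one passed at 1.65 (adjusted p = 0.0467). In the insulin-like growth factor axis (13 genes, median 0.02, adjusted p = 0.645), Igfbp3, Igfbp2, Peg3 and Igf2 had log2 fold changes of -2.16, 1.56, 0.96 and 1.82 and did not pass (adjusted p = 0.0559, 0.0830, 0.0812 and 0.166). A dimmer Igfbp3 probe set, at the floor in aged cells, passed at -2.01 (adjusted p = 0.0467). Proteasome genes had 26 of 32 negative (median -0.14, adjusted p = 0.157, and 0.0268 at that floor), and cholesterol biosynthesis 10 of 13 (median -0.28, adjusted p = 0.235). These medians shrank to -0.07 without adult replicate 1 and to -0.10 without aged replicate 1. Heat shock genes and chaperones had a median of 0.02 over 34 genes (adjusted p = 0.271), antioxidant genes 0.08 over 33 (adjusted p = 0.324), and secreted inflammatory factors -0.08 over 11 (adjusted p = 0.384). Of the inflammatory factors 37 were on the array, so most were too dim to be tested.

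Of the marker lists for other cell types, only that of smooth muscle and pericytes passed, in 8 of 13 alternatives at the preset correlation and not with an estimated one (adjusted p = 0.447). Fibroblast markers had 8 of 11 genes positive and a median of 0.09 (camera adjusted p = 0.195), which was 0.21 without adult replicate 2. Postn rose, and Col3a1 and Pdgfra had log2 fold changes of 1.22 and -1.07 (adjusted p = 0.0812 and 0.183). Macrophage markers had a median of 0.23 over 9 genes (adjusted p = 0.472), Schwann cell markers 0.46 over 5 (adjusted p = 0.472), and endothelial markers 0.02 over 6 (adjusted p = 0.645), of which Eng rose. Leaving out single arrays moved these medians to between 0.034 and 0.24, -0.35 and 0.55, and -0.24 and 0.74. Only 4 lymphocyte and red cell markers were measured, with a median of -0.19, so that list was not tested.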

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

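The tests of fibroblasts and of differentiation were chosen only after the result was seen.

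Among control probe sets on the arrays that enter no comparison, 3 had all values of 1 age at least 1.25 times those of the other. The probe set for the murine B1 repeat gave 41856 ± 6210 on the adult and 62269 ± 4575 on the aged arrays (SD, n = 2), a ratio of 1.49. The 3' probe set of pyruvate carboxylase gave 281 ± 52.3 and 433 ± 44.1, a ratio of 1.55, while its 5' probe set gave 426 ± 53.2 and 429 ± 71.8. The 3' probe set of the bacterial bioB spike gave 645 ± 70.6 and 410 ± 16.2, a ratio of 0.637, while its 5' probe set gave 345 ± 6.93 and 334 ± 142. The 12 probe sets of the bacterial Dap, Lys, Phe and Thr transcripts had a median log2 ratio of 0.00, from -0.25 to 0.18. That median covers a split by position. The 3' probe sets of Dap, Lys and Phe had aged to adult ratios of 1.12, 1.13 and 1.12. Their 5' probe sets had 0.843, 0.953 and 0.886. Thr had 0.977 at the 3' and 0.995 at the 5' end. The cause was not tested.

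Muscle differentiation genes were higher and cell cycle genes lower in the aged cultures. A bias with signal level is argued against, since 0 of 10000 random lists matched on level had a median as far from 0 as either list. Fibroblasts in place of myoblasts would lower muscle genes. Of the 40 measured, 32 had a positive log2 fold change. Both aged values lay above both adult values in 28 and below them in 4. These values argue against that explanation for the muscle genes. For the cell cycle genes it stays open. Myoblast identity genes did not fall as a group (median 0.16), and their median lay 0.71 above that of the cell cycle genes. Its permutation p was 1e-05, the smallest that 100000 resamples can give, with genes treated as independent. Fibroblasts divide too, so cell cycle genes need not fall with a loss of myoblasts, and this comparison cannot decide. The fibroblast markers' own median lay below that of the muscle genes without passing (permutation p = 0.138). Also open is a hypothesis that more cells of the aged cultures had left the cycle and begun to differentiate. Cdkn1a would then be higher and Myf5 lower. On both aged against both adult arrays 2 of their 3 probe sets were, and none passed in limma. The remaining 1, of Cdkn1a, was not separated (log2 fold change 0.29, adjusted p = 0.708). These genes therefore do not decide whether more cells had left the cycle. Whether that may come from the age of the mice or from the state of the cultures at harvest, such as their density, was not tested, because each age has only 2 arrays and the labels give no culture details.

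Of the 66 probe sets that passed, 28 had an age at the floor on both arrays. A candidate explanation is that the floor removes the spread of that age and so lowers the p-value. Among probe sets with as large a change, 42.4% of those that passed had an age at the floor, against 22.6% of those that did not (Fisher's exact p = 0.00247, two-sided). For 31 passing probe sets all 4 values lay above the floor, so the floor did not remove their own spread. The variance estimate of eBayes is shared over all probe sets tested, so the floor can still affect their p-values. When only probe sets above the floor on all arrays were tested, 108 passed. The direction of a gene at the floor in 1 age is a measured difference, and its p-value is the part that stays open.

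Both brighter probe sets annotated to Ctse had a log2 fold change above 2, at 3.33 and 2.46. The annotation gives these 2 probe sets 1 source sequence and the third another. The third lay below the floor on all 4 arrays, so the probe sets disagree, and no value here decides which of them reads the gene.

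A probe set with no gene listed had the lowest log2 fold change among passing probe sets without a single symbol, -3.82, from 101235 ± 7854 to 7219 ± 1162 (adjusted p = 0.0265).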

How the results depend on the processing

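The floor at the 30th percentile of the values above 0 and the run on probe sets above the floor on all arrays were chosen after seeing the data. The count of 66 passing probe sets stayed within 1.5 times under quantile normalization (72), equal medians (65), the floor at the 30th percentile of all values (66) or of the values above 0 (95, with all 12422 probe sets tested, since that floor lies above the filter), and a pseudocount (79). It became 118 with no filter, where more probe sets were tested, 351 with the filter at the 60th percentile, 108 on probe sets above the floor on all arrays, 476 with a variance trend and 10 with a plain equal-variance test, and the cause was not tested. Without each array in turn it was 0 to 0 in limma (903 to 1996 at unadjusted p under 0.05), with fewer arrays and the lone one assumed to vary like the other age. The count of 284 probe sets 2-fold apart in all pairs became 146 with the filter at the 60th percentile and 168 above the floor on all arrays, where fewer were tested, 742 at 1.5-fold, 108 at 3-fold, and 440 to 684 without each array in turn, where fewer pairs must hold. The 7 passing lists became 0 with an estimated correlation, 11 with fry, which asks another question (TGF-beta and BMP signalling, antioxidant, oxidative phosphorylation, cholesterol and endothelial genes gained, glycolysis lost), and 4 to 6 without each array in turn, with 4 without adult replicate 2. Muscle differentiation, cell cycle and extracellular matrix passed camera in 14 of 14 alternatives at the preset correlation. Values that turned sign were Wnt10b (from -0.42 to 0.036 without each array in turn, the last without adult replicate 1), Cdkn2a (from -0.55 to 0.027, the last without aged replicate 2), and other probe sets of Atp5d (-0.10) and Mtm1 (0.58, adult at the floor), and the cause was not tested. Without 1 array, values of genes that did not pass moved by over 1.5 times for Myod1 (-0.16 to -0.047), Cebpa (0.091 to 0.42), Cdkn1a (0.25), Tagln (0.41), Apc (0.43), Pdgfra (-0.70) and Igf2 (1.17). Medians of lists that did not pass also turned sign, most from near 0. Heat shock genes gave -0.0041 under quantile normalization, -0.020 with the filter at the 60th percentile, -0.015 above the floor on all arrays and -0.0032 with the mean of a gene's probe sets. Endothelial markers gave -0.014 with a pseudocount and Schwann cell markers -0.016 with no filter. Without each array in turn the medians ran from -0.031 to 0.076 for TGF-beta and BMP signalling, -0.11 to 0.12 for Wnt signalling, -0.20 to 0.0068 for secreted inflammatory factors, -0.15 to 0.10 for the insulin-like growth factor axis, -0.24 to 0.74 for endothelial and -0.35 to 0.55 for Schwann cell markers. Other medians near 0 that moved by over 1.5 times without an array were those of heat shock (0.0041 to 0.077), oxidative phosphorylation (0.054 to 0.096) and antioxidant genes (0.063 to 0.13). With no filter, smooth muscle and growth arrest medians fell to 0.32 and 0.21. Of the other values for single genes, 1168 kept direction and side of the threshold, 195 no longer passed and 58 newly passed, and for lists, without a turn of sign, 314, 25 and 9. The floor at the 10th percentile of all values (-166) has no log and was not run. Signal at or below the floor, 37.1% to 37.9% of each array, limits what can be said of dim genes.

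With the replicate number as a replicate block, 0 probe sets passed in limma (1426 at unadjusted p under 0.05) and the same number of lists, 7, passed. That fit leaves fewer residual degrees of freedom than the planned one, which by itself raises the p-values. The 0 therefore does not show a replicate effect. Over all tested probe sets, same-numbered arrays did not deviate together (correlation of deviations from the group means -0.05). That does not exclude a shared effect on some probe sets. Replicate 1 had the higher maximum at both ages, 150209 against 126022 for adult and 160387 against 134402 for aged arrays.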

Other observations

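The 5 gene groups below were listed after the main results were seen, and the tests of serum response factor targets, hypoxia targets and imprinted genes were chosen only after some of their genes' values were seen.

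Genes controlled by serum response factor outside the muscle list, which act in the actin cytoskeleton or respond early to growth signals, had 20 of 28 positive log2 fold changes in the aged myoblasts and a median of 0.42. A hypothesis is that these targets moved together, which camera gave at an adjusted p of 9.41e-05 over the 5 groups but not with an estimated correlation (adjusted p = 0.202). Ccn2 and Acta2 passed, and the next by unadjusted p were Csrp1, from 1750 ± 61.2 to 3674 ± 167 (SD, n = 2; log2 fold change 1.07), and Fos, from 261 ± 30.9 to 505 ± 3.54 (0.96), with limma adjusted p = 0.0620 and 0.0805. The abundant actin genes Actg1 and Actb had log2 fold changes of -0.02 and 0.55 and did not pass (adjusted p = 0.954 and 0.517). The adult arrays lay far apart for Actb (22060 ± 10282), and the brighter control probe sets of beta-actin had aged to adult ratios of 0.761 to 0.845. The group shares Acta2, Tagln and Cnn1 with the smooth muscle markers, so the shift may not be independent of theirs.

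The hypotheses that other groups moved together did not hold. Hypoxia targets had 10 of 17 positive and a median of 0.30 (camera adjusted p = 0.131), histones 2 of 6 and -0.33 (adjusted p = 0.131), ribosomal proteins 14 of 22 and 0.06 (adjusted p = 0.131), and imprinted genes 8 of 15 and 0.20 (adjusted p = 0.260). Within the imprinted genes, Ndn, Peg3 and Igf2 had log2 fold changes of 1.29, 0.96 and 1.82, and Mest had -1.24, from 5675 ± 376 to 2403 ± 11.7, with limma adjusted p = 0.0533 for Ndn and Mest, 0.0812 for Peg3 and 0.166 for Igf2. A second Ndn probe set was below the floor on both adult arrays and at 942 ± 176 on the aged arrays (log2 fold change of 2.32 against the floor).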
